A study of Mus musculus with 2 samples.

How the data were processed

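The series holds 10x Genomics Visium CytAssist libraries from formalin-fixed, paraffin-embedded mouse small intestine. In this assay, pairs of probes hybridise to the transcripts of a tissue section, are ligated and then captured on a grid of barcoded spots, so that each count carries a gene, a spot and a molecule tag (unique molecular identifier, UMI). A spot covers several cells, and probes report only the genes of the panel. Each of the 2 diets has 1 section, 5 µm thick, of wild-type small intestine. The labels give neither the part of the small intestine nor the sex of the animals.

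The deposited matrices hold whole-number UMI counts per gene and spot, with no normalization, for spots over tissue only. Counting was done with Space Ranger against mm10, per the submitters' processing notes, and the version of the program is not given in the sources used here. Both matrices list the same 19465 genes. The deposited position tables place every spot on a grid of 4992, of which 3894 lay over tissue in the control section and 3952 in the HFD section. The scale factors of the tissue image were not used here, and no image was analysed. No column of the files went unused for lack of a sample.

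Counts were summed over all spots of a section and scaled to a total of 1000000 per section (CPM). The control section held 52770307 UMIs and the HFD section 56257402. A level of 10 CPM corresponds to 528 UMIs in the control section and 563 in the HFD section. The ratio of the HFD section to the control section was given an exact conditional binomial 95% interval, and a level an exact Poisson interval. These intervals cover counting error only. With 1 section per diet there is no spread between animals, so no test was run, no p-value is given, and spots were never treated as replicates. Every ratio compares these 2 libraries, not the diets. Gene counts used genes at 10 CPM or more in at least 1 section and a 2-fold limit. Of 2 panel entries with the same symbol (11 symbols), the one with the higher count was used for lists.

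The gene lists were fixed before the data were examined. There were 45 lists with 637 different genes. The 5 primary lists were fat absorption, fatty acid oxidation, cholesterol synthesis, antimicrobial genes and MHC class II. The 16 secondary lists were lipogenesis, carbohydrate digestion, peptide digestion, bile acids, cholesterol uptake and export, xenobiotic metabolism, retinoids, iron and heme, interferon response, inflammation, type 3 immunity, junctions, mucus, endoplasmic reticulum (ER) stress, cell death and the respiratory chain. The 18 cell marker lists covered enterocytes, crypt stem cells, proliferation, Paneth, goblet, enteroendocrine and tuft cells, T cells, B cells, plasma cells, myeloid cells, smooth muscle, fibroblasts, endothelium, enteric nerve, adipose tissue with mesothelium, pancreas and blood. A further 4 lists covered early stress genes, the circadian clock, and proximal and distal gut, and 2 more held villus tip and crypt genes that set an axis. For each list the median log2 ratio of the members at 10 CPM or more was placed among the medians of 10000 random lists of the same size, drawn gene by gene from the 100 genes of nearest mean level. The percentile describes these libraries only. A counting interval of each median came from 1000 Poisson draws of the counts. The same medians were also computed between the left and right and the upper and lower parts of each section, split at the median spot position.

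Genes are named by a rule fixed at the same time. It took the 12 highest and 12 lowest ratios among genes at 50 CPM or more and at least 1.5-fold apart, the 4 members of each list farthest from a ratio of 1, and in each compared region the 5 highest and 5 lowest ratios at 100 CPM or more. It also took Cd36, Fabp1, Apoa4, Scd1, Hmgcs2, Reg3b, Reg3g and H2-Ab1 in any case. Members named beyond this rule were chosen after their values were seen.

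Spots of both sections were clustered together with the Leiden method (leidenalg 0.10.2 on igraph 0.11.9, resolution 0.5, 15 neighbours, 15 principal components of log counts per 10000) on 174 cell marker and axis genes that are in no primary or secondary list. Regions are called by their leading genes, and those with 50 or more spots in each section were compared. No doublet caller and no deconvolution was run. The clustering used genes that themselves differed between the sections. A second clustering, chosen after seeing the data, therefore standardized each of these genes within each section first and is called the section-standardized clustering. The share of tip genes in the sum of tip and crypt genes gave each spot a coordinate, which was divided into 5 bins by pooled quintiles over the spots of epithelial regions. A region of the first clustering counted as epithelial if its 10 leading genes held more epithelial than other markers. Those led by Hist1h3b and Uhrf1, by Ly6m, Nt5e and Ada, and by Pyy and Cck did. Those led by Jchain and Igha (1493 control and 571 HFD spots) and by Ms4a18 and Reg1 (299 and 969) did not. Quintiles taken within each section were added after seeing the data, over the spots of epithelial regions and over all spots outside the muscle and adipose regions of the section-standardized clustering.

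The alternatives fixed before the data were examined were scaling by the median of ratios, totals without the 50 most abundant genes, a 50 CPM filter, no level filter, spots with at least 1000 UMIs only, the mean of spot CPM, spots thinned to equal median depth, equal region shares, epithelial regions only, a clustering resolution of 1.0, clustering on 3000 variable genes and 3 bins. Added afterwards were both section-standardized settings, the within-section quintiles, and a setting without the region led by Car3, Cfd and Adipoq. Gene coordinates are those of GRCm38 (mm10) from the RefSeq gene table, matched by symbol for 19106 panel symbols. The steps ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. On simulated sections with the real library sizes and 19465 genes, 200 of them altered by 3-fold or 4-fold, the 2-fold limit recovered 100% of the altered genes at each size and took 0 of the unaltered ones, and 94.0% of the intervals held the true ratio. The simulated sections held counting error only, with no spread between animals, places or libraries, and the altered genes had a mean level of 10 CPM or more. Recovery was therefore all but fixed in advance. It checks the calculation and says nothing of how reliable the gene counts below are.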

Results

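Spatial gene expression was measured in the small intestine of wild-type mice on 2 diets. One diet was rich in stearic acid, a saturated fatty acid of 18 carbons, and drew 54.8% of its energy from fat (HFD). The control diet drew 10% of its energy from fat. Feeding began at 4 weeks of age and lasted 2 weeks. Each diet had 1 section and no replicate, so the values below compare these 2 sections and have no check against the spread between animals. The control section had 3894 spots over tissue with a median of 13168 UMIs and 4184.5 genes per spot. The HFD section had 3952 spots with a median of 13526 UMIs and 4382 genes. In total 52770307 UMIs were counted in the control section and 56257402 in the HFD section, so that for most genes counting error was small beside the differences described. Intervals in brackets are 95% and cover counting error only.

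**Figure D1:**
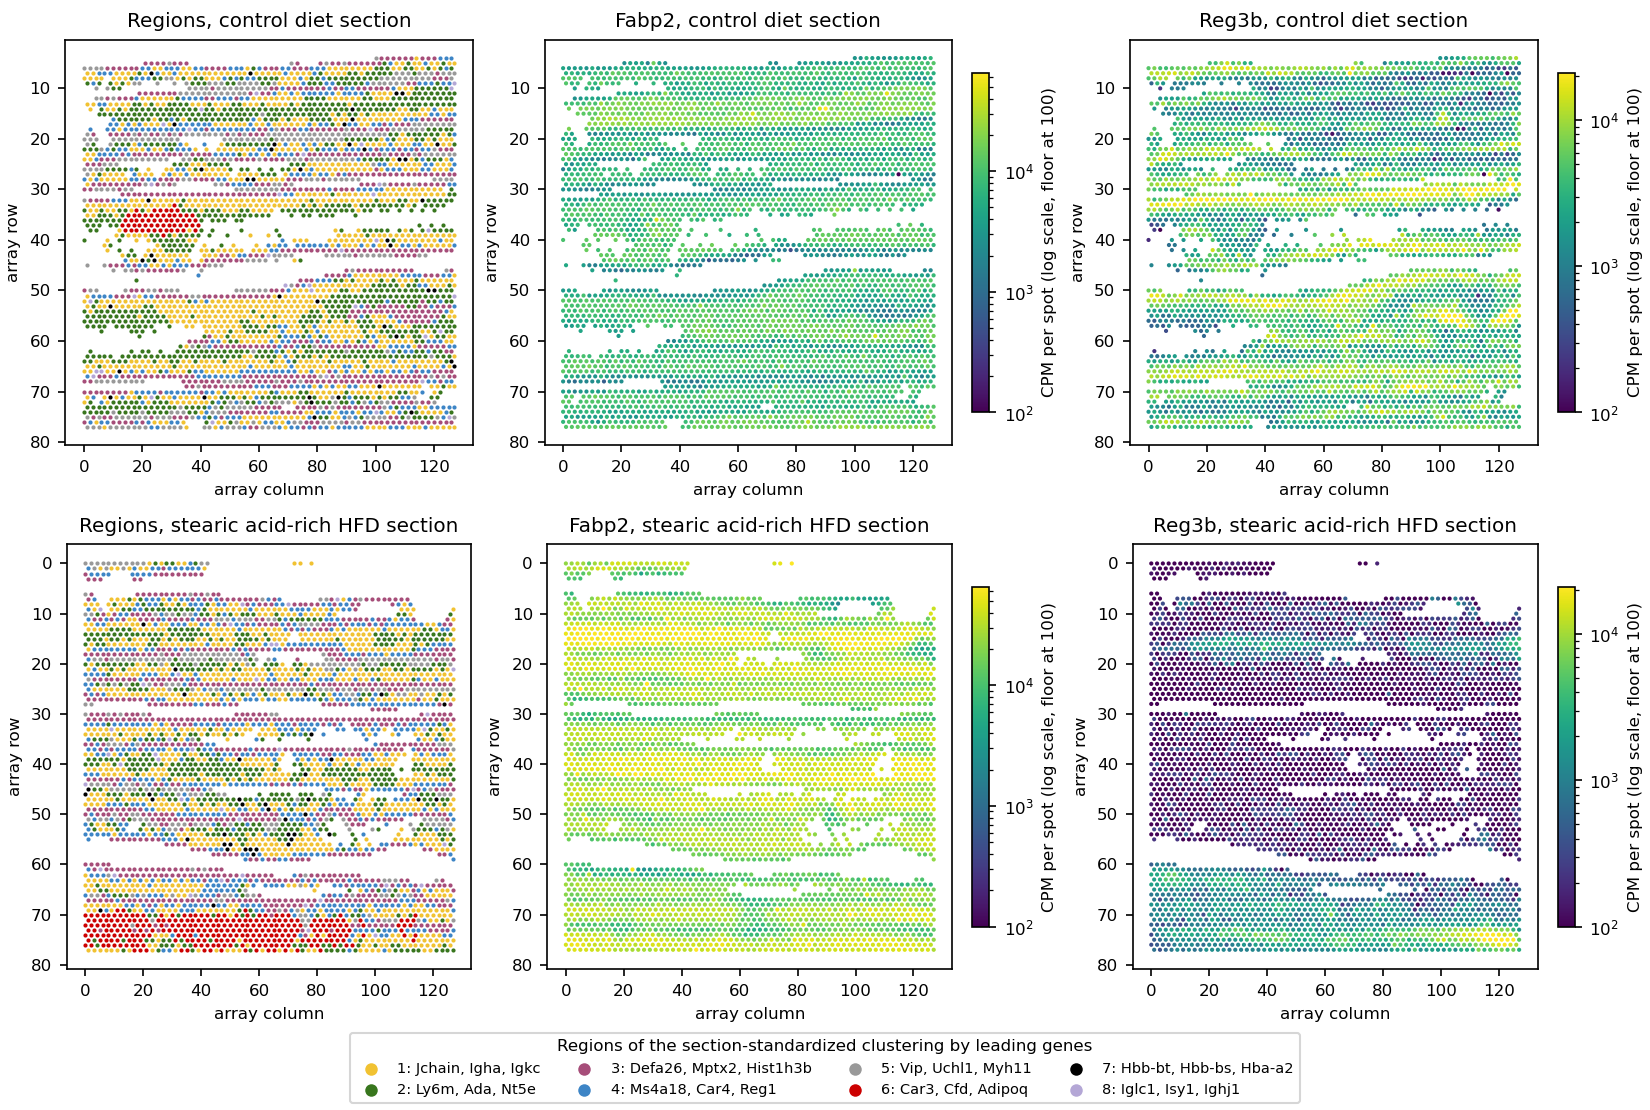
Capture spots over tissue of the control section (top) and the HFD section (bottom), placed by array column and array row, coloured by region of the section-standardized clustering (left) and by the CPM of Fabp2 (middle) and Reg3b (right) in each spot on a log colour scale with a floor at 100. Fabp2 was higher across the HFD section (28045 against 9085 CPM over the whole sections), and Reg3b was lower there (824 against 5762 CPM), with its highest levels there in the last array rows.

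The whole-section comparison asked which transcripts differed in level between the small intestine of mice on the HFD and on the control diet. Among genes at 50 CPM or more, H2-Q10, Ces1f, Akr1c19, Acot1 and Tm4sf4 had the highest ratios of the HFD section to the control section. Bco1, Npl, AA467197, Slc28a2 and Lama3 had the lowest. Of 8892 genes at 10 CPM or more, 372 were at least 2-fold higher in the HFD section and 263 at least 2-fold lower, while 6839 (76.9%) lay within 1.5-fold. The balance of higher and lower genes depended on scaling: with median-of-ratios scaling the counts were 216 and 369, because that scaling moved the median log2 ratio of all genes by -0.16, from 0.08 to -0.08.

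The highest of these ratios was that of H2-Q10, a nonclassical MHC class I gene (ENSMUSG00000067235, chromosome 17, 35470089 to 35474563, GRCm38). Its level was 3.51 CPM in the control section and 114 CPM in the HFD section, a ratio of 32.4 (28.0 to 37.8). Enzymes made up most of the next genes. The carboxylesterase Ces1f was 29.0-fold higher, the aldo-keto reductases Akr1c19 and Akr1c13 were 26.0-fold and 8.81-fold higher, and the aldehyde dehydrogenases Aldh1a7 and Aldh1a1 were 6.23-fold and 5.52-fold higher. The acyl-CoA thioesterase Acot1 was 14.9-fold higher (13.2 to 16.9). Hmgcs2, the rate-limiting enzyme of ketone body synthesis (chromosome 3, 98280431 to 98310738), was at 17.1 CPM in the control section and 94.1 CPM in the HFD section, a ratio of 5.50 (5.13 to 5.91). The tetraspanin-related gene Tm4sf4 was the most abundant of this group, at 151 and 2153 CPM (14.2-fold). The others were the laminin chain Lamb3 (7.21-fold), Insig1, a regulator of sterol synthesis (5.75-fold), and the carbonic anhydrase Car4 (5.46-fold). Without the probe sequences, probes of 1 gene binding transcripts of a close relative could not be excluded, so values of single members of the Akr1c, Aldh1a, Ces1, Reg3 and Defa families were not shown to be free of signal from relatives.

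At the other end, Bco1, which cleaves beta-carotene to retinal (ENSMUSG00000031845, chromosome 8, 117095851 to 117133720), was at 54.6 CPM in the control section and 0.693 CPM (39 UMIs) in the HFD section. The control level was 78.8-fold higher (57.5 to 111). Reg3b, a C-type lectin with antibacterial activity (chromosome 6, 78370885 to 78373466), was at 5762 CPM in the control section and 824 CPM in the HFD section, 6.99-fold lower. This level depended on place within the HFD section: array rows 69 to 77 held 3509 CPM of Reg3b and the remaining rows 350 CPM. Several lower genes are known from the villus tip, among them the nucleoside transporter Slc28a2 (1101 and 107 CPM, 10.3-fold), the ectonucleotidase Nt5e (7.03-fold) and Ly6m (6.64-fold). The laminin chain Lama3 was 9.03-fold lower, the reverse of Lamb3. Npl (152 and 13.8 CPM), AA467197 (10.3-fold), Tmem140 (94.1 and 12.5 CPM), the chemokine gene Ccl5 (7.04-fold), the aldose reductase family gene Akr1b7 (107 and 15.4 CPM) and Apol9b (6.57-fold) were the others.

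**Figure D2:**
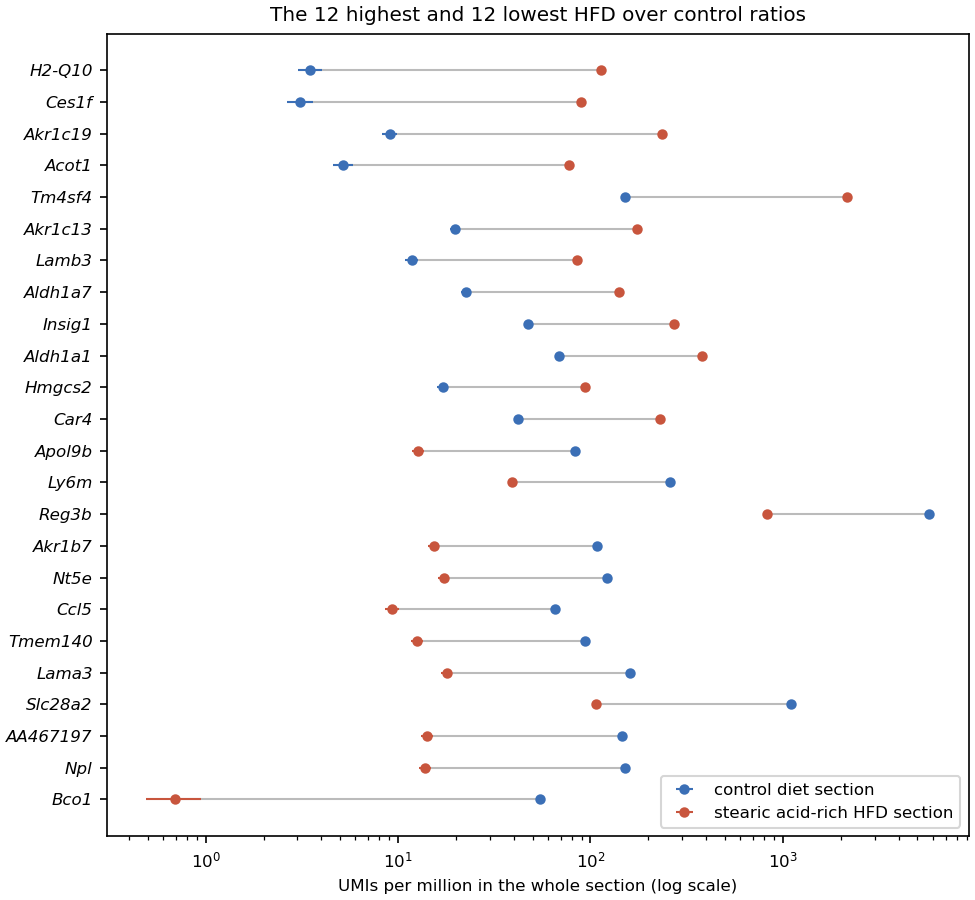
Level in CPM on a log axis of the 12 genes with the highest and the 12 with the lowest HFD over control ratio, in the control section (blue) and the HFD section (red), with exact Poisson 95% intervals, mostly narrower than the points. The ratios run from 32.4-fold higher in the HFD section for H2-Q10 to 78.8-fold lower for Bco1.

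Genes of fat absorption went both ways, with fatty acid-binding protein genes higher in the HFD section and several abundant lipoprotein genes lower. The median of its 27 members was 0.40 on the log2 scale (0.37 to 0.41), above 99.9% of random lists. At least 1.5-fold higher were 7 members and at least 1.5-fold lower 4, with 16 within 1.5-fold. Fabp2, the intestinal fatty acid-binding protein, was at 9085 and 28045 CPM in the control and HFD sections (3.09-fold), and Fabp1, the liver-type protein, at 749 and 1872 CPM (2.47-fold to 2.53-fold higher). Mttp, which loads lipid onto apolipoprotein B, was 2.19-fold higher and the acyl-CoA synthetase Acsl5 2.60-fold higher, while Cd36, a fatty acid transporter, was 1.41-fold higher (1.36 to 1.47). The lower members were Scarb1 (30.0 and 2.26 CPM, 13.3-fold), Apoc3 (4400 and 1110 CPM, 3.96-fold), Apob (2.47-fold) and Apoa1 (21485 and 11169 CPM, 1.92-fold), whereas Apoc2 was 3.18-fold higher. Apoa4 was at 11962 and 11478 CPM, a log2 ratio of -0.06 that became 0.74 with equal region shares and 0.23 with equal shares of the section-standardized regions.

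Genes of fatty acid oxidation were higher in the HFD section, with a median log2 ratio of 0.52 (0.49 to 0.56), above 99.99% of random lists. Of 29 members, 13 were at least 1.5-fold higher and 1, the pantetheinase gene Vnn1, was at least 1.5-fold lower (1.95-fold). After Acot1 and Hmgcs2, the highest were Acadl, a long-chain acyl-CoA dehydrogenase (85.6 and 345 CPM, 4.03-fold), and the thioesterase Acot2 (3.13-fold). Cpt1a, which commits fatty acids to entry into mitochondria, was 2.61-fold higher, and Cpt2 2.12-fold. Lipogenesis genes were higher as well, with a median of 0.69 and 8 of 14 members at least 1.5-fold higher. Me1 was 6.71-fold higher, the stearoyl-CoA desaturases Scd2 and Scd1, which place a double bond in stearic acid, 5.08-fold and 4.06-fold, and Acacb 3.73-fold. Most control UMIs of Scd1 lay in a patch of spots led by adipose genes, and without that region the log2 ratio of Scd1 was 3.81 instead of 2.02.

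The cholesterol synthesis list had the highest median of the 21 primary and secondary lists, at 1.48 (1.45 to 1.53), above all 10000 random lists. Of its 22 members 19 were at least 1.5-fold higher in the HFD section and 0 were at least 1.5-fold lower. Insig1 was 5.75-fold higher, Pcsk9 5.23-fold, the lanosterol demethylase Cyp51 4.51-fold and the mevalonate kinase gene Mvk 4.05-fold. The low-density lipoprotein receptor gene Ldlr was 3.68-fold higher, and Hmgcr, the rate-limiting enzyme of the pathway, 1.82-fold. Cholesterol uptake and export genes went the other way, with the lowest median of the same lists, -1.47 (-1.52 to -1.37). Abca1 was 3.78-fold lower, the cholesterol uptake gene Npc1l1 was at 1665 and 442 CPM (3.77-fold lower), and the sterol exporter genes Abcg8 and Abcg5 were 2.95-fold and 2.72-fold lower. Nr1h3, a sterol-sensing receptor gene of the same list, was 1.72-fold higher. The labels do not give the cholesterol content of the diets, which bears on both lists.

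**Figure D3:**
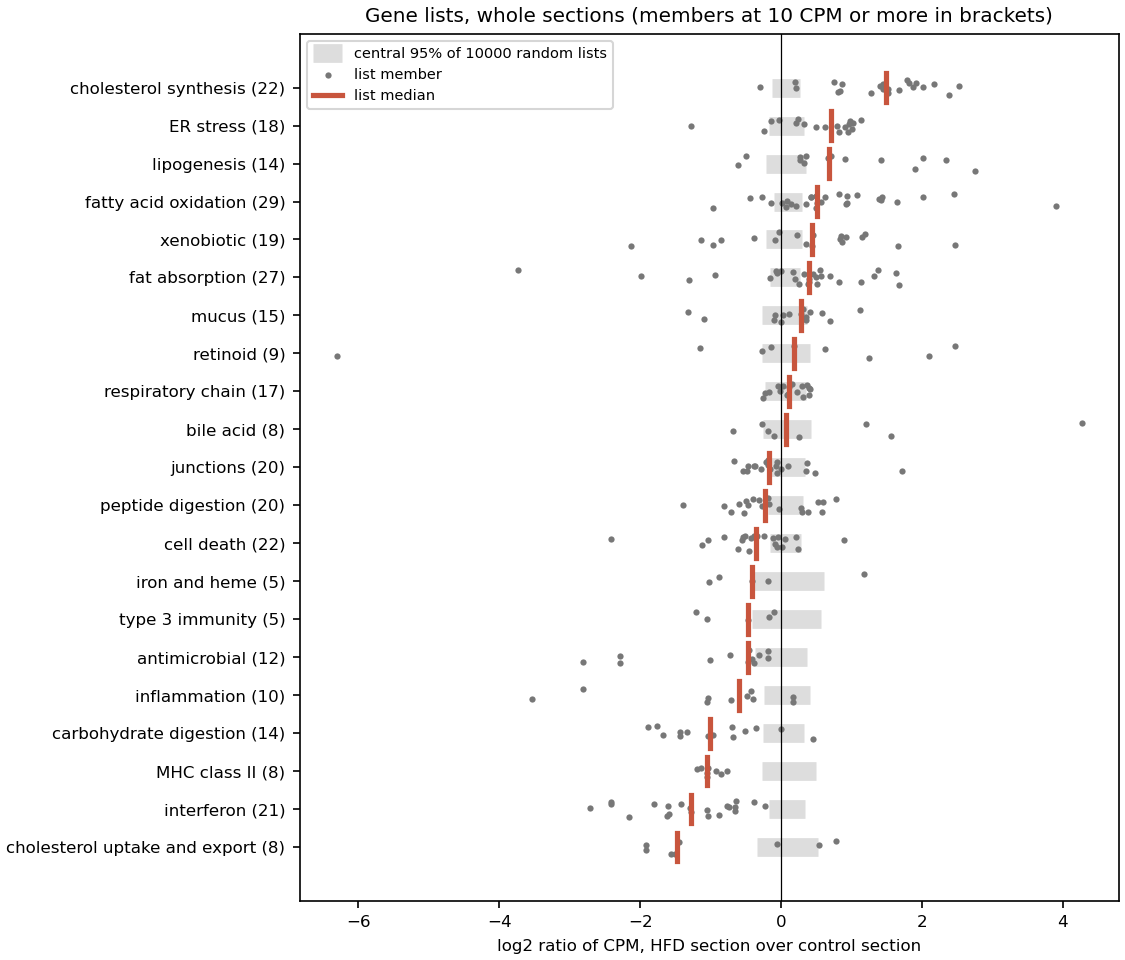
Log2 ratio of CPM, HFD over control section, for each member at 10 CPM or more (grey points) of the 21 primary and secondary lists, with the list median (red bar) and the central 95% of medians of 10000 random lists matched on level (grey band). Medians run from -1.47 for cholesterol uptake and export to 1.48 for cholesterol synthesis.

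Sugar digestion genes were lower in the HFD section. The carbohydrate digestion list had a median of -1.0 (-1.05 to -0.95), below all 10000 random lists, with 10 of 14 members at least 1.5-fold lower and 0 at least 1.5-fold higher. The disaccharidase genes Mgam and Sis were 3.70-fold and 3.38-fold lower, with Sis at 4949 and 1463 CPM. The glucose transporter genes Slc5a1 and Slc2a2 were 3.20-fold and 2.71-fold lower. Peptide digestion genes differed less, with a median of -0.23. In that list the peptide transporter gene Slc15a1 was 2.61-fold lower and the aminopeptidase gene Anpep 1.71-fold higher.

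Antimicrobial genes were lower in the HFD section, with none of 12 members above the control level. The median was -0.47 (-0.50 to -0.44), above 0.96% of random lists, and 5 members were at least 1.5-fold lower. The median was nearer to 0 with equal shares of the section-standardized regions (-0.15) and in epithelial regions only (-0.27), where the region led by Hist1h3b and Uhrf1 held 438 control and 1037 HFD spots and that led by Ly6m, Nt5e and Ada 813 and 16, so that unlike mixes were compared. The 5 members were the lectin genes Reg3b (6.99-fold), Reg1 (4.88-fold), Reg3g (5672 and 1161 CPM, 4.88-fold) and Reg3a (1.66-fold), and the ribonuclease gene Ang4 (2.01-fold). Over whole sections 2 other Paneth cell products were nearer to the control level, the defensin gene Defa24 (1.31-fold lower) and lysozyme, Lyz1 (1.14-fold lower). Within regions Paneth cell markers went both ways. Their median was -0.80 in the region led by Hist1h3b and Uhrf1, with 6 of 7 at least 1.5-fold lower. It was 0.36 in the section-standardized region led by Ly6m, Ada and Nt5e. In array rows 69 to 77 of the HFD section Reg3g reached 4156 CPM, against 632 CPM in its other rows.

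MHC class II genes were lower in the HFD section in 8 of 8 members, each by at least 1.5-fold. The median was -1.04 (-1.07 to -0.97), above 0.01% of random lists. H2-Ab1 (chromosome 17, 34263227 to 34269418) was at 200 and 88.1 CPM, 2.28-fold lower (2.20 to 2.35), H2-DMa 2.20-fold lower, H2-Aa 2.08-fold and H2-DMb1 2.07-fold. Cd74, the invariant chain, was at 771 and 406 CPM, and Ciita, the regulator of the class II genes, was 1.70-fold lower. Interferon response genes were lower too, with a median of -1.27 and 19 of 21 members at least 1.5-fold lower. Ifit1 was 6.56-fold lower, Zbp1 5.34-fold, Ifit1bl1 5.34-fold and Oas3 4.47-fold. The inflammation list had a median of -0.59, with Nos2 11.6-fold lower, Ccl5 7.04-fold and Duoxa2 and Il18 2.07-fold and 2.05-fold, and type 3 immunity a median of -0.46, with Rorc 2.30-fold and the antibody transporter gene Pigr 2.07-fold lower. T cell markers reached 10 CPM in 3 cases, and Ccl5, Gzma (57.1 and 9.30 CPM) and Cd3e (11.1 and 3.43 CPM) were all lower, with a median of -2.62. All 3 passed this limit through the control section alone, so the limit favoured that direction. At a resolution of 1.0 the T cell median was below 0 in 10 of 10 regions. In the one led by Jchain, Igha and Igkc, where 9 markers passed, it was -0.61, with 5 at least 1.5-fold lower.

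ER stress genes were higher in the HFD section, with a median of 0.71 (0.69 to 0.73) and 10 of 18 members at least 1.5-fold higher. The chaperone genes Creld2, Hsp90b1 and Pdia4 were 2.20-fold, 2.03-fold and 2.01-fold higher and Hspa5 1.95-fold, while Atf3 was 2.44-fold lower. Xenobiotic metabolism genes had a median of 0.44, with 8 of 19 members at least 1.5-fold higher and 4 at least 1.5-fold lower. Aldh1a1, Nqo1 (3.15-fold) and Gstm3 (2.29-fold) were higher, and the cytochrome gene Cyp3a11 was 4.36-fold lower. Retinoid genes went both ways, so that the median was 0.18 and the mean -0.14. Rbp2, which carries retinol in enterocytes, was at 2804 and 12071 CPM, 4.31-fold higher, in contrast to Bco1. Bile acid genes had a median of 0.07 and a mean of 0.75, and the sign of the median turned to -0.08 with median-of-ratios scaling. In that list the ileal bile acid transporter gene Slc10a2 was 19.2-fold higher (1.86 and 35.7 CPM), Nr0b2 2.94-fold and Abcc3 2.31-fold higher, and Fgf15 1.61-fold lower.

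The remaining secondary lists went both ways. Medians were -0.41 for iron and heme, where Tfrc was 2.27-fold higher and Slc40a1 2.02-fold lower, and -0.36 for cell death, where Fas was 2.18-fold and Bcl2l11 2.05-fold lower. They were -0.17 for junctions, where Cldn2 was 3.30-fold higher and Cldn15 1.58-fold lower, and 0.29 for mucus, where Agr2 was 2.18-fold higher and Muc3 and Muc13 were 2.49-fold and 2.14-fold lower. The respiratory chain had a median of 0.12 with 17 of 17 members within 1.5-fold, and the sign turned to -0.04 with median-of-ratios scaling.

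Markers of proliferating cells were higher in the HFD section, and markers of tuft cells and T cells lower. All 12 proliferation genes were at least 1.5-fold higher, with a median of 1.02 (0.97 to 1.07) and Cdk1 2.53-fold and Birc5 2.31-fold higher. Over regions of the fixed clustering the proliferation median was 0.70, above 0 in 7 of 7, and over section-standardized regions 1.26. Proliferation genes helped to draw these regions. Without the region led by Car3, Cfd and Adipoq the 2 values were 0.58 and 1.04. In the region led by Hist1h3b and Uhrf1 the proliferation median was 0.47, with 1 of 12 members at least 1.5-fold higher. The 3 tuft cell markers at 10 CPM, Sh2d6, Hck and Ptgs1, were 3.18-fold, 2.82-fold and 1.73-fold lower. The villus tip list had a median of -1.17, with Ada 3.92-fold lower, and the crypt list 0.81. Over regions of the fixed clustering, which genes of these lists helped to draw, the 2 lists were at -0.28 and 0.55. Over section-standardized regions they were at -0.79 and 0.97. Goblet cell markers had a median of 0.33, enteroendocrine markers 0.27, with Gip 1.82-fold lower, Paneth cell markers -0.39 and enterocyte markers -0.31. Within regions the last 2 did not keep their sign: enterocyte markers were above 0 in 5 of 7 regions of the fixed clustering, and Paneth cell markers in 3 of 6 of the section-standardized clustering. Crypt stem cell markers had a median of -0.05 and a mean of 0.05, with Olfm4 at 459 and 598 CPM.

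Markers of cells outside the epithelium went both ways. Medians were -0.13 for B cells (1 gene), 0.06 for plasma cells (mean -0.08), -0.15 for myeloid cells (mean 0.03), -0.19 for smooth muscle, -0.41 for endothelium and -0.28 for enteric nerve. Fibroblast markers had a median of 0.00, and with median-of-ratios scaling it was -0.16 and with totals without the 50 most abundant genes -0.06, while that of plasma cells became -0.09. Adipose markers had a median of 1.34 from 3 genes, blood 0.32 from 2 and pancreas -0.58 from Clps alone. Among quality lists, early stress genes had a median of -0.15, with Jun 2.71-fold lower and Hsph1 2.95-fold higher, and clock genes -0.37, with 12 of 13 members lower and Nr1d1 1.68-fold lower. Proximal gut genes had a median of -0.33, with Lct 2.53-fold lower and Fabp1 higher, and distal gut genes -0.23, with Slc10a2 higher and Clca4b 1.74-fold lower.

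The largest difference of a list median between the left and right or upper and lower parts of either section was 0.09 for fat absorption, 0.10 for fatty acid oxidation, 0.08 for cholesterol synthesis, 0.24 for antimicrobial genes and 0.18 for MHC class II. These parts are large, and the labels do not say how the gut was laid out in a section, so they do not bound what place can do. Between narrower places of the HFD section Reg3b differed 10.0-fold and Reg3g 6.57-fold, more than between the sections. For adipose markers such parts differed by up to 5.77, for smooth muscle by 0.68, for enteric nerve by 0.56, for blood by 1.11 and for B cells by 0.47, more than the sections did. The same held for fibroblasts (0.13), plasma cells (0.11), crypt stem cells (0.09) and bile acid genes (0.08).

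The region comparison asked whether these differences held within regions led by the same genes. Cholesterol synthesis and fatty acid oxidation genes were higher and MHC class II genes lower in the HFD section in each region compared. With the clustering fixed beforehand, 7 regions had enough spots in both sections, led by Jchain and Igha (plasma cell genes), by Hist1h3b and Uhrf1 (proliferation), by Ms4a18 and Reg1, by Vip and Myh11 (nerve and muscle), by Pyy and Cck (enteroendocrine), by Car3, Cfd and Adipoq (adipose tissue) and by Hbb-bs and Hba-a2 (hemoglobin, beside immunoglobulin genes). The cholesterol synthesis and fatty acid oxidation medians were above 0 in 7 of 7 regions, with medians over regions of 1.13 and 0.56. The MHC class II median was below 0 in 7 of 7, with -0.77 over regions. Fat absorption was above 0 in 6 and antimicrobial genes below 0 in 6, with 0.64 and -0.68 over regions. The exception in both was the region led by adipose genes, which in the HFD section also held crypt and Paneth cell genes: there Defa21 was at 497 CPM in the control section and 11613 CPM in the HFD section. It is therefore not a like part of the tissue, and without it the medians over the other 6 regions were 1.13, 0.58, -0.76, 0.68 and -0.85 for cholesterol synthesis, fatty acid oxidation, MHC class II, fat absorption and antimicrobial genes, each with 1 sign in 6 of 6 regions.

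Single genes repeated this within regions. Akr1c19 and Tm4sf4 were among the 5 highest ratios in 6 of the 7 regions and H2-Q10 in 5. In the region led by Jchain and Igha, H2-Q10 was 41.5-fold higher (33.2 to 52.4) and Scd1 14.3-fold higher (12.2 to 16.9). In the region led by Hist1h3b and Uhrf1, Reg3b was 15.4-fold lower (6870 and 446 CPM), Reg3g 8.14-fold lower and Rbp2 5.15-fold higher. In the region led by Pyy and Cck, Npl was 9.32-fold lower and Akr1b7 7.76-fold lower. A region led by Ly6m, Nt5e and Ada held 813 control spots and 16 HFD spots and was not compared. Because its leading genes were themselves lower in the HFD section, these numbers say nothing of how much villus tip tissue each section held.

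With the section-standardized clustering, chosen after seeing the data, a region led by Ly6m, Ada and Nt5e held 974 control and 640 HFD spots, and 6 regions were compared. The cholesterol synthesis, fatty acid oxidation and ER stress medians were above 0 in 6 of 6 regions, and the MHC class II, interferon, carbohydrate digestion, inflammation and cholesterol uptake and export medians below 0 in 6 of 6. Here too the region led by Car3, Cfd and Adipoq (59 and 284 spots) held different tissue in each section, and without it the counts were 5 of 5. The other regions were not fully alike either: among the genes that drew them, the crypt list stood at 1.27 and the tip list at -1.23 in the region led by Ly6m, Ada and Nt5e, and smooth muscle markers at -0.71 in the region led by Vip and Uchl1. In the region led by Ly6m, Ada and Nt5e the cholesterol synthesis median was 1.87, beside 1.64 for proliferation markers, and in the region led by Defa26, Mptx2 and Hist1h3b it was 0.96, beside 0.65. Antimicrobial genes were not uniform, at -0.95 in the latter region and 0.22 in the former.

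**Figure D4:**
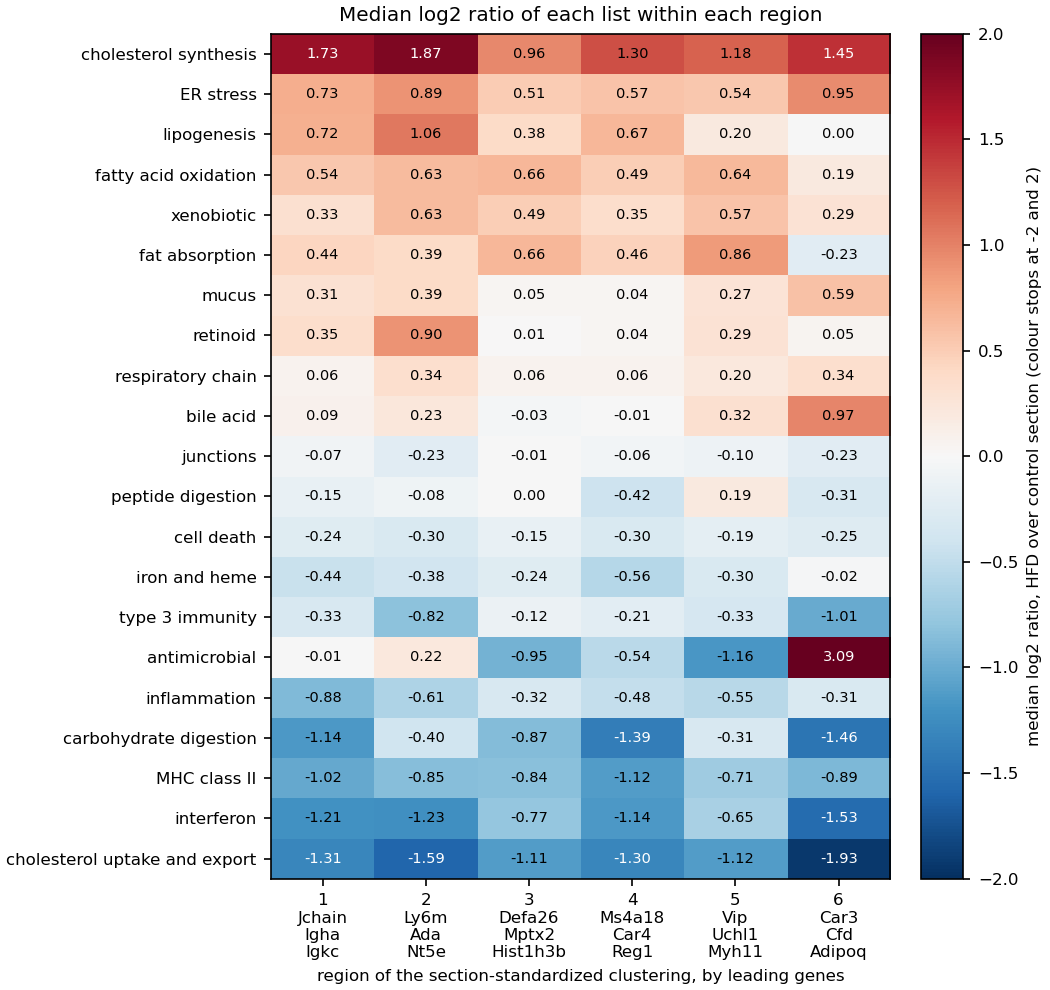
Median log2 ratio, HFD over control section, of the 21 primary and secondary lists (rows) within the 6 compared regions of the section-standardized clustering (columns, by their leading genes), as colour and number. Cholesterol synthesis was above 0 and MHC class II below 0 in each region, and antimicrobial genes were at 3.09 in the region led by Car3, Cfd and Adipoq.

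The profile from crypt to villus asked where along this axis the levels differed. In both sections the lipid transport genes Fabp2, Rbp2 and Apoa4 were higher toward the tip, and Hmgcs2 toward the crypt. From the lowest to the highest fixed bin, Fabp2 went from 3099 to 10184 CPM in the control section and from 13922 to 45089 CPM in the HFD section, so that it stood higher in the HFD section at both ends. Hmgcs2 went from 38.6 to 5.23 CPM in the control section and from 174 to 37.4 CPM in the HFD section. Scd1 went from 39.7 to 148 CPM in the HFD section, and in the control section it was at 9.0 and 5.90 CPM with overlapping intervals (5.24 to 14.4 and 4.11 to 8.21). Insig1 showed 49.2 and 59.7 CPM against 175 and 439 CPM, and Hmgcs1, the cytosolic enzyme of cholesterol synthesis, 169 and 89.5 CPM against 329 and 417 CPM. Sis went from 4082 to 2688 CPM in the control section and from 1007 to 1453 CPM in the HFD section. Reg3b went from 7413 to 1995 CPM in the control section and lay at 398 and 307 CPM in the HFD section, and Cd74 was higher at the tip in both, at 392 and 791 CPM against 256 and 630 CPM. The highest fixed bin held 535 control and 49 HFD spots, since the tip genes that set the coordinate were lower in the HFD section. Quintiles within each section over the same spots gave the same directions for these genes except Reg3b in the HFD section, then at 300 and 560 CPM, leaving aside Scd1 and Insig1 in the control section, whose intervals at the ends overlapped. When they also took in more spots, Reg3b there was at 438 and 689 CPM and Insig1 in the control section at 47.8 and 47.5 CPM.

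**Figure D5:**
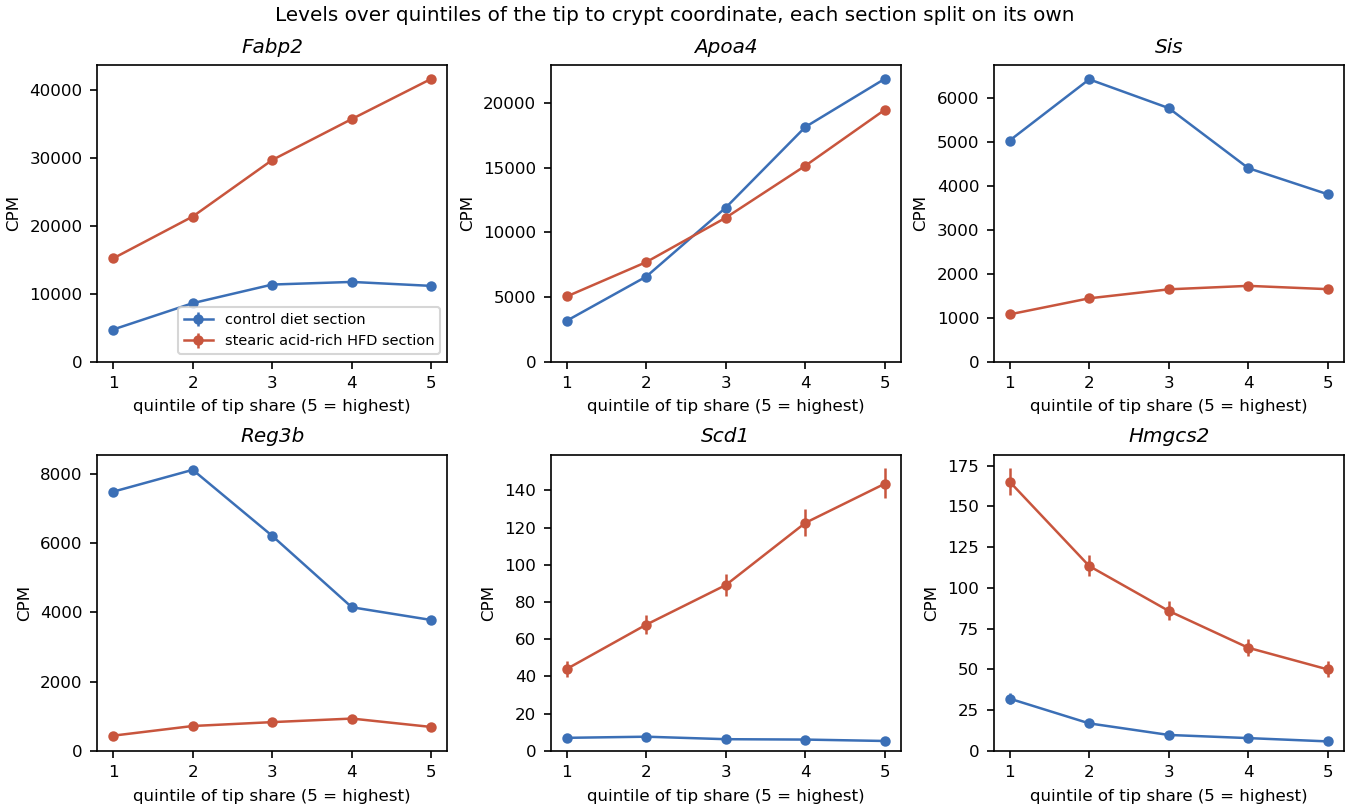
CPM of 6 genes over quintiles of the share of tip genes, taken within each section over spots outside muscle and adipose regions (1 lowest, 5 highest), in the control section (blue) and the HFD section (red), with exact Poisson 95% intervals. Fabp2 reached 41715 CPM in the highest quintile of the HFD section and 11164 CPM in that of the control section, and Hmgcs2 was highest in the lowest quintile of both.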

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

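Each comparison rests on 1 section per diet, so differences between animals, between places along the gut and between library preparations cannot be separated from diet. No test was run. A paired analysis was not possible with 1 section per diet, and the labels give no pairing. Over the 11 alternatives run on whole sections, the 5 primary lists kept the sign of their median in 55 of 55 values, 30 named genes in 328 of 330 (the exceptions are for Apoa4) and the other 40 lists in 406 of 435. The named genes include the 12 highest and 12 lowest ratios, each at least 5.46-fold. No alternative moved the median log2 ratio of all genes by more than 0.16. Most signs of the named genes were therefore all but fixed by how these genes were picked. The settings chosen after seeing the data were the section-standardized clustering, equal shares of its regions, the setting without the region led by Car3, Cfd and Adipoq, and both settings with within-section quintiles. Clustering on 3000 variable genes gave no region with 50 spots in both sections and so no value.

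Where the cause is not named below, the cause was not tested. Genes at least 2-fold higher numbered 372 at first and 216 with median-of-ratios scaling, 194 with equal region shares and 680 in epithelial regions only, a setting that compares unlike mixes of crypt-led and tip-led spots. A 50 CPM filter tested fewer genes and gave 170 higher and 145 lower, and no level filter tested more and gave 1049 and 395. With totals without the 50 most abundant genes the counts were 319 and 320. Median-of-ratios scaling shifted all lists together, to 0.24 for fat absorption, 0.36 for fatty acid oxidation, 1.33 for cholesterol synthesis, -0.62 for antimicrobial genes and -1.20 for MHC class II. Totals without the 50 most abundant genes gave 0.34, 0.45, 1.42 and -0.53 for the first 4 of these. Equal region shares gave 0.62, 0.59, 1.36, -0.53 and -0.73 for the 5 lists. Epithelial regions only gave 0.19 for fat absorption, 0.63 for fatty acid oxidation and -0.27 for antimicrobial genes. With no level filter, which adds scarce members, fatty acid oxidation was at 0.57 and MHC class II at -0.93. Equal shares of the section-standardized regions gave 0.45 for fat absorption, -0.15 for antimicrobial genes and -0.91 for MHC class II. Without the region led by Car3, Cfd and Adipoq antimicrobial genes were at -0.55. Over regions, a resolution of 1.0 gave 0.68 for fat absorption, 0.63 for fatty acid oxidation and 1.42 for cholesterol synthesis, and the section-standardized clustering gave 0.45 for fat absorption, 1.37 for cholesterol synthesis, -0.27 for antimicrobial genes and -0.87 for MHC class II. From the lowest to the highest bin of the HFD section, Reg3g had a log2 ratio of 0.41 with within-section quintiles of the same epithelial spots, reversed from the fixed bins, and 0.0719 when more spots were also used, while Reg3b had 0.90 and 0.65. Depth limits little at 10 CPM, but Bco1 in the HFD section rests on 39 UMIs, and only 3 of 14 T cell markers reached 10 CPM.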

Other observations

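The last array rows of the HFD section differed from the rest of it. The band described here, rows 69 to 77, held 576 spots. It was set to begin at the first row with a spot of the region led by Car3, Cfd and Adipoq. All 284 HFD spots of that region therefore lay in it by construction, and Cfd and Car3 were among the genes that drew the region. Beside adipose genes (Cfd at 368 CPM there and 2.74 CPM in the other rows), several epithelial genes were higher in this band. Fgf15, the hormone that the ileum releases in response to bile acids, was at 55.2 CPM in the band and 7.51 CPM elsewhere (7.35-fold, 6.39 to 8.46), and Slc10a2 at 61.2 and 31.2 CPM. Over the control section Fgf15 was at 23.6 CPM and Slc10a2 at 1.86 CPM. The phospholipase gene Plb1 was 5.00-fold higher and Reg3b 10.0-fold higher in the band, where Reg3b reached 3509 CPM against 5762 CPM over the control section. Fabp2 was at 30004 and 27700 CPM in the same places. These genes were chosen after their values were seen. Several of them also led regions of control spots. In the clustering on variable genes, a region of 95 control spots was led by Plb1, Fam151a, Tmigd1, Iglc3, Fgf15 and Mgat4c. Another of 27 control spots was led by Cfd, Car3, Scd1 and Adipoq. A region of 329 HFD spots was led by Reg3b, Car3, Cfd, Fgf15 and Plb1. The control levels given here cover the whole section, so the band was not compared with a like place there.

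Genes at least 2-fold apart lay near another gene of the same direction more often than in random draws, though most did not. Of 364 higher genes with coordinates, 89 had another higher gene within 200 kb, against a median of 62 and a highest of 84 over 200 random draws from the genes tested. Of 261 lower genes, 65 had such a neighbour, against a median of 34 and a highest of 56. Akr1c13 and Akr1c19 on chromosome 13 and Aldh1a1 and Aldh1a7 on chromosome 19 are examples, and since they belong to families of similar sequence, shared probe signal between them was not excluded.

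Of the tests in the paragraphs below, only the one on tip-enriched genes was written down before its result was seen, without a level limit; its tip region came from the section-standardized clustering, chosen after seeing the data, and its limit was moved from 50 to 10 CPM after a first result (33 of 119 genes at or above the control level); the other tests, and a condition on the spread of members used for the immune cell and the stem and Paneth cell markers, were set after values had been seen.

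MHC class II, interferon and T cell genes were lower in the HFD section. A sequence variant at the H2 locus on chromosome 17 that acts only on genes there cannot account for the whole. The 24 members elsewhere had a median log2 ratio of -1.28 (-1.34 to -1.22), against -1.05 for the 8 on chromosome 17. The interferon and T cell lists had been seen to be lower before this test was set, so its outcome was known. It leaves open whether a variant lowered the class II genes on chromosome 17. H2-Q10, also on chromosome 17 and the highest ratio among genes at 50 CPM or more, was 32.4-fold higher. Fewer immune cells of every kind under the capture area would lower plasma cell, B cell and myeloid markers alike, but these 15 had a median of -0.13 (-0.18 to -0.01), with 1 at least 1.5-fold lower. Sections from different places along the gut cannot be told apart from diet here, because the distal list had a median of -0.23 and the proximal list -0.33, and the distal members went both ways. Fewer intraepithelial T cells with less interferon signalling to the epithelium under the HFD may be a candidate explanation, which 1 section per diet cannot test.

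Villus tip genes were lower and proliferation genes higher in the HFD section. More crypts under the capture area would raise stem and Paneth cell markers with proliferation, but these 13 had a median of -0.19 (-0.23 to -0.15), against 1.02 for proliferation. This cannot decide whether more crypts are a cause. The same markers were lower within the region led by Defa26 and Mptx2 (below), so their level may not measure the number of crypts. Other values go with more crypts. The crypt list was at 0.81 (6 of its 9 members are proliferation genes). Stem and Paneth cell markers were higher in the section-standardized regions led by Jchain and Igha (0.41 and 0.45) and by Ly6m, Ada and Nt5e (0.39 and 0.36). They were lower in that led by Defa26 and Mptx2 (-0.32 and -0.81), which held 17.3% of control and 21.1% of HFD spots. In the fixed clustering the region led by Hist1h3b and Uhrf1 held 11.2% and 26.2%, with proliferation at 0.47 there. Proliferation genes helped to draw both regions. Fewer villus tips would lower nearly all genes enriched there, yet 31.1% (24.2% to 38.8%, exact binomial) of 167 genes enriched in the control tip region were at or above the control level. This interval takes the genes as independent, which genes of 1 pair of sections are not, and does not cover counting error. It reaches below the 25% set in advance, so this stays open. The 167 genes had a median log2 ratio of -0.45, against 0.08 for all genes at 10 CPM or more, so as a set they were lower. A faster renewal of the epithelium under the HFD, with cells leaving the tip program earlier, could give such a pattern and was not tested.

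Bco1 and Scarb1 were lower and Isx higher in the HFD section. The transcription factor ISX is known to repress both genes in response to retinoic acid, and repression where Isx is higher predicts that all 3 differ together in place. In 6 of 6 regions of the section-standardized clustering Isx was higher (in the region led by Ly6m, Ada and Nt5e 9.05 and 32.0 CPM) and Bco1 and Scarb1 were lower, but the whole-section ratios of Bco1 and Scarb1 all but fixed this outcome, so it lends repression by ISX no support and leaves it open. Retinoic acid acting on all of its targets would raise the other responsive genes too, and 2 of 4 were higher, with log2 ratios of 0.18 for Dhrs3 and 0.53 for Cyp26b1 against -1.15 for Lrat and -0.50 for Rarb, but Cyp26b1 and Rarb lay below 10 CPM and so this decides nothing. A difference in the vitamin A or carotenoid content of the diets, which the labels do not give, or in the place along the gut remains open, so this is a hypothesis for follow-up.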
